A study of Homo sapiens with 5 samples.

How the data were processed

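RNA was measured by droplet-based single-cell sequencing in gastruloids grown from H1 human embryonic stem cells and edited derivatives. Per the labels, cells were pretreated with 3.25 µM CHIR99021, a GSK3 inhibitor that activates Wnt signalling, for 24 hours. The aggregates then grew in 0.5 µM for 72 hours before dissociation with Accutase. Libraries were made with the 10x Genomics 3′ v3.1 dual index kit at a target of 10000 cells each, per the labels' protocols. The labels gave 5 libraries: WT 2, KO 1 and DATG 2. They give neither the sequence removed in KO or DATG nor a batch.

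The authors deposited UMI counts per gene and cell barcode for each library, with no normalization, per the file headers. Reads were processed with Cell Ranger 8.0.1 on GRCh38 per the submitters' processing notes, while the headers name version 8.0.0. Whether barcodes were filtered before deposit is not stated. The 5 tables shared 36601 genes with Ensembl identifiers and symbols. CPM, percentages of cells, log2 fold changes and p-values were all computed here from the deposited counts. Coordinates came from GENCODE release 29 on GRCh38, which matched 27885 of the tested genes (95.3%).

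A barcode was kept with at least 1000 detected genes and at most 20% of UMIs from mitochondrially encoded genes. Doublets were scored in each library against simulated doublets, and the highest-scoring 0.8% per 1000 cells were removed (4.94% to 9.36% of the barcodes passing the filter). Counts per cell were scaled to 10000 and log-transformed, and 2000 variable genes, 30 principal components and 20 nearest neighbours fed Leiden clustering at resolution 0.6, with no batch correction. Mitochondrially encoded, ribosomal protein, X-inactivation and Y-linked genes were left out of the variable genes. Clusters were named from 13 cell type marker lists by their 10 leading genes, with the detected share of each list as a second rule. Clusters far shallower than their own libraries, matching more than 1 class, or led by a marker of a class with under 3 detected markers, stayed unnamed. Free RNA was not removed, so single UMIs in a cell need not come from it. Shares carry exact binomial (Clopper-Pearson) intervals, UMI rates exact Poisson intervals, and a count of 0 was read as a limit of 3 counts; these cover counting error only.

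Cells are not replicates, so UMI counts were summed over the kept cells of each library. The sums were compared with edgeR's quasi-likelihood F-test, TMM factors and filterByExpr, with group as the only term, over all 5 libraries. The p-values were adjusted by Benjamini-Hochberg and read at 0.05. The fit had 2 residual degrees of freedom, a prior of 3.14 and a common biological coefficient of variation of 0.132. KO has 1 library and is assumed to vary like the other groups. CPM of single genes used TMM effective library sizes, except for LNCPRESS1, given as CPM of kept UMIs without a factor. The summed counts held 77.3% and 83.4% of the deposited UMIs for WT replicates 1 and 2, 84.5% for the library labelled KO and 81.7% and 81.8% for DATG replicates 1 and 2. Gene lists were tested with camera at a preset correlation of 0.01, with the estimated correlation and fry beside it, adjusted over 32 lists. Shares of classes were tested with edgeR on cell numbers, with all kept cells as library size, over 6 classes. Genes within a class were tested in classes with at least 50 cells in every library compared. With 2 libraries against 2, a permutation test cannot reach 0.05.

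The 32 lists were the 13 cell type lists (pluripotent epiblast, primitive streak, presomitic mesoderm, somite, caudal neuromesodermal, neural, neural crest, cardiac and lateral plate mesoderm, endothelial and blood, definitive endoderm, notochord, amnion and surface ectoderm, germ cell) and 19 others. The others were Wnt, Nodal and Activin, BMP, FGF and ERK, Notch, retinoic acid, HOX, p53, glycolysis, oxidative phosphorylation, mitochondrially encoded, ribosomal protein, proliferation, hypoxia, dissociation stress, integrated stress response, transition, matrix and imprinted genes. Named genes were LNCPRESS1, the 8 largest increases and 8 largest decreases among genes past the threshold with a mean of at least 10 CPM and no overlap of libraries, and up to 3 members of each list that passed. Within a class 3 of each direction were named. Groups, tests, lists, the naming rule and most alternatives were fixed before the data were examined.

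The fit was tested on simulated data drawn from these libraries' means, with 200 genes changed by a known size. For DATG against WT 2, 107 and 187 of the 200 were recovered at log2 changes of 0.5, 1 and 2, with 4, 20 and 38 false calls. For the library labelled KO against WT 0, 54 and 158 were recovered (0, 9 and 19 false calls), and against DATG 0, 40 and 156 (0, 6 and 24 false calls). Changes of 0.5 were thus rarely recovered. At changes of 1 and 2, false calls were a larger part of all calls than the adjusted p threshold allows, in each comparison. At 0.5 in DATG against WT they outnumbered the recovered genes (4 against 2). The adjusted p-values may therefore understate the share of false calls among the genes called.

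Alternatives were DESeq2 size factors, no count filter, all barcodes, a stricter cell filter (2000 genes, 10% mitochondrial), doublets kept, equal weight per cell, thinning to 22228.5 UMIs, a replicate block, each library left out, DESeq2, limma-voom, glmTreat against log2 0.5 and the estimated correlation. For classes they were resolution 1.2, components centred by library, at least 500 genes with doublets kept, and TMM factors. Chosen after seeing the data were cells with at least 10000 UMIs, leaving out short-arm genes of chromosome 12 and leaving out cells with over 1.9% of UMIs on that arm. The arm was taken as the first 35 Mb, with 520 genes. Sex-linked marker genes were not named in the results here, but they stayed among the genes tested and in the counts of genes that passed. Tools were Python 3.11.15 (numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, igraph 0.11.9, leidenalg 0.10.2, matplotlib 3.10.9) and R 4.3.3 (edgeR 4.0.16, limma 3.58.1, DESeq2 1.42.0).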

Results

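Single-cell RNA was counted in gastruloids, which are 3D aggregates that human pluripotent stem cells form under brief Wnt activation and that hold derivatives of the early germ layers. The cells came from H1, an established human embryonic stem cell line, and fell into 3 groups named for the long noncoding RNA lncPRESS1. WT, with the unedited locus, had 2 libraries, KO had 1 and DATG, named for a deleted ATG start codon, had 2. Each library was a 10x Genomics 3′ v3.1 library. The deposited tables held 300974073 UMIs over 15603 barcodes in WT replicate 1 and 480557324 over 11951 in WT replicate 2. The library labelled KO held 214322658 over 17222, and the DATG libraries held 544493952 over 13531 and 484315307 over 14295. After filtering, 10476 and 9432 WT cells, 5870 cells of the library labelled KO and 10095 and 10599 DATG cells were kept. Their median depths were 22228.5, 37521, 27364.5, 39333 and 34065 UMIs in that order. In the library labelled KO 54.2% of barcodes held under 1000 genes, against 22.3% and 8.07% in WT and 13.9% and 14.1% in DATG.

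The replicates of the groups differed in how close they were. Over 9842 genes with a mean of at least 10 CPM (counts scaled to a fixed library size), the SD of the log2 difference between libraries was 0.04 for the DATG pair and 0.32 for the WT pair. WT replicate 2 lay nearer to the DATG libraries (0.24 for each) than to WT replicate 1. The labels give no batch, but the submitters' name for WT replicate 1 marks it as a pilot, so a batch of that library cannot be told apart from spread within WT. The DATG libraries share 1 designation, and the labels do not say whether they are separate cultures. If they are 1 culture, DATG has n = 1 and its SDs are technical. KO has 1 library, so every KO comparison assumes that it varies like the other groups.

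LNCPRESS1, the gene the lines are named for (ENSG00000232301), lies on the plus strand of chromosome 7 from 101299578 to 101301346 in GRCh38. Exon 1 ends at 101299866 and exon 2 starts at 101300769. Its level was lowest in WT and DATG and highest in the library labelled KO, which goes against that label. It stood at 0.0430 CPM of kept UMIs in WT replicate 1 (10 UMIs; 95% exact Poisson interval 0.0206 to 0.0791) and 0.0399 in WT replicate 2 (16 UMIs; 0.0228 to 0.0648). The DATG libraries gave 0.0382 (17 UMIs; 0.0223 to 0.0612) and 0.0505 (20 UMIs; 0.0308 to 0.0780). The library labelled KO gave 0.651 (118 UMIs in 101 cells; 0.539 to 0.780), above each of the other 4 libraries. The log2 fold change of that library was 3.79 over WT (SE 0.28, edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.00107) and 3.70 over DATG (SE 0.27, edgeR adjusted p = 0.00111). DATG and WT did not differ detectably (log2 0.09, SE 0.31, edgeR adjusted p = 0.935), and this small value changed sign under several settings, down to −0.32.

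Most of the LNCPRESS1 molecules of the library labelled KO, 102 of 118 (86.4%), lay in pluripotent-like and streak-like cells. Its pluripotent-like cells held 2.85 CPM (74 UMIs; 2.24 to 3.58), and 11.9% of those 506 cells had a LNCPRESS1 UMI at a median depth of 48545.5 UMIs. Among its 323 mesoderm-like cells, which should lack this RNA of pluripotent cells, 1 cell (0.310%) had a UMI at a median depth of 30363. That single UMI gives 0.0944 CPM (0.00239 to 0.526), an interval that holds the mesoderm-like levels of WT (0.0463 and 0.0447). No WT cell was pluripotent-like, so the gene could not be compared between WT and the library labelled KO within the class that holds most of it. In streak-like cells that library held 0.377 CPM (28 UMIs), under the upper limit of 2.67 for WT replicate 2 (0 UMIs). In endoderm-like cells it held 0.182 CPM (7 UMIs), under the limits of 0.536 and 0.382 for WT (0 UMIs each). These counts are too few to tell the libraries apart. The labels do not give the deleted part, and 3′ tags from outside a deletion check nothing about it. The name "the library labelled KO" is used throughout for this reason, and every direction drawn from it below rests on that label.

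**Figure D1:**
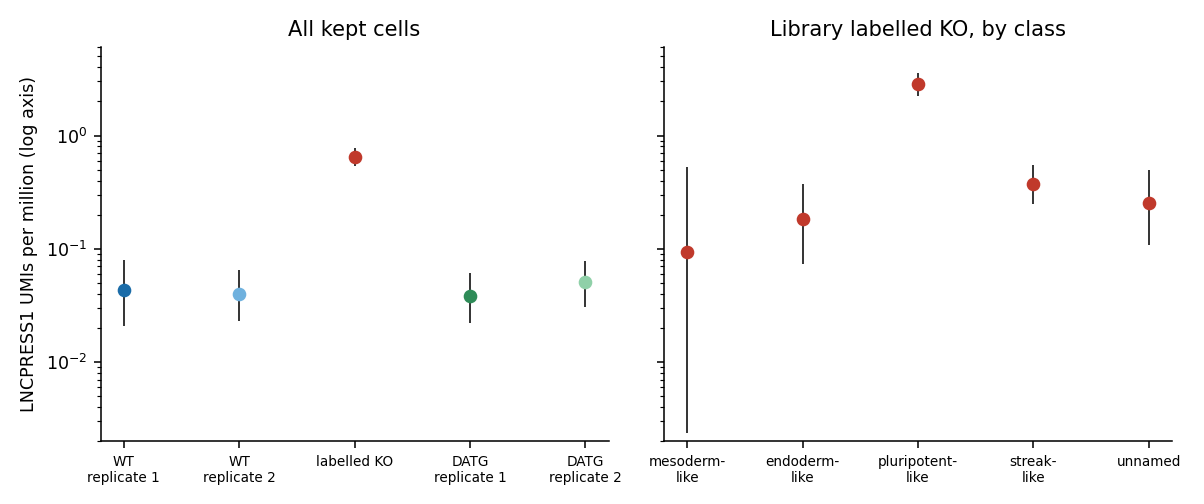
CPM of LNCPRESS1 (log axis) in each library's kept cells (left, colours by library) and in the classes of the library labelled KO that held any (right); bars are 95% exact Poisson intervals. The library labelled KO stands at 0.651 and its pluripotent-like cells at 2.85, while the WT and DATG libraries lie between 0.0382 and 0.0505.

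The kept cells formed 19 clusters, of which 13 were named from markers fixed in advance. Mesoderm-like cells, with cardiac and lateral plate markers such as HAND1 and TBX20, made up 55.1% and 78.8% of the WT libraries (67.0% ± 16.7, SD, n = 2) and 77.3% and 76.9% of the DATG libraries (77.1% ± 0.332, SD, n = 2). They made up 5.50% of the library labelled KO (exact 95% binomial interval 4.93% to 6.12%). This share depends on how clusters are drawn, and was 31.3% at resolution 1.2 and 33.0% with library-centred components. Of this class only cluster 7 had list markers among its leading genes (MYL7 and TNNT2). The other clusters of the class were named by the second rule, with at least 50% of the list detected at 20 CPM or more. Endoderm-like cells (SOX17, APOA2) made up 1.58% ± 0.202 of WT (SD, n = 2), 3.72% ± 0.0429 of DATG (SD, n = 2) and 17.8% of the library labelled KO (16.8% to 18.8%). At resolution 1.2 this class largely split by library. A cluster led by SOX17 and PRDM1 held 652 cells labelled KO and 0 and 0 WT cells. A cluster with APOA1 and APOA2 among its leading genes held 37 labelled KO and 160 and 124 WT cells. Endothelial- or blood-like cells (ERG, ETV2, LMO2) made up 1.81% ± 0.596 of WT, 1.25% ± 0.0910 of DATG (SD, n = 2 each) and 0 of the 5870 cells labelled KO, which allows a share of up to 0.0511%. Cells with primitive streak markers (MESP1, LHX1) made up 30.5% of the library labelled KO (29.3% to 31.7%), 0.0191% and 0.339% of WT and 0.367% and 0.292% of DATG. Their cluster also held the mesoderm marker HAND1 at 1039 CPM, and its size depends on how clusters are drawn. It held 1791 cells labelled KO here, 1081 at resolution 1.2 and 2102 with library-centred components. At resolution 1.2 a cluster with 713 cells labelled KO was named mesoderm-like instead. Pluripotent-like cells (POU5F1, ESRG) made up 8.62% of the library labelled KO (7.91% to 9.37%). There was 1 such cell in each DATG library and none in WT, which allows up to 0.0286% and 0.0318%. The pluripotent-like cluster also had the highest streak genes MIXL1 (357 CPM), EOMES (197) and TBXT (104) of the 19 clusters. Its name therefore does not mean cells free of streak genes. Unnamed clusters held 41.7% and 17.2% of WT, 37.6% of the library labelled KO and 17.3% and 17.9% of DATG. In WT replicate 1 they were mostly the shallow clusters 8 (2054 cells) and 5 (2013 cells). In WT replicate 2 and DATG they were mostly cluster 6 (57.1%, 57.6% and 58.0% of the unnamed cells). It is not shallow and has TNNT2 at 262 CPM and MYL7 at 287 CPM, so the mesoderm-like shares leave out cells with cardiac genes. In the library labelled KO they were mostly a cluster of 1938 cells with LINC00698 and LGR5 among its leading genes.

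**Figure D2:**
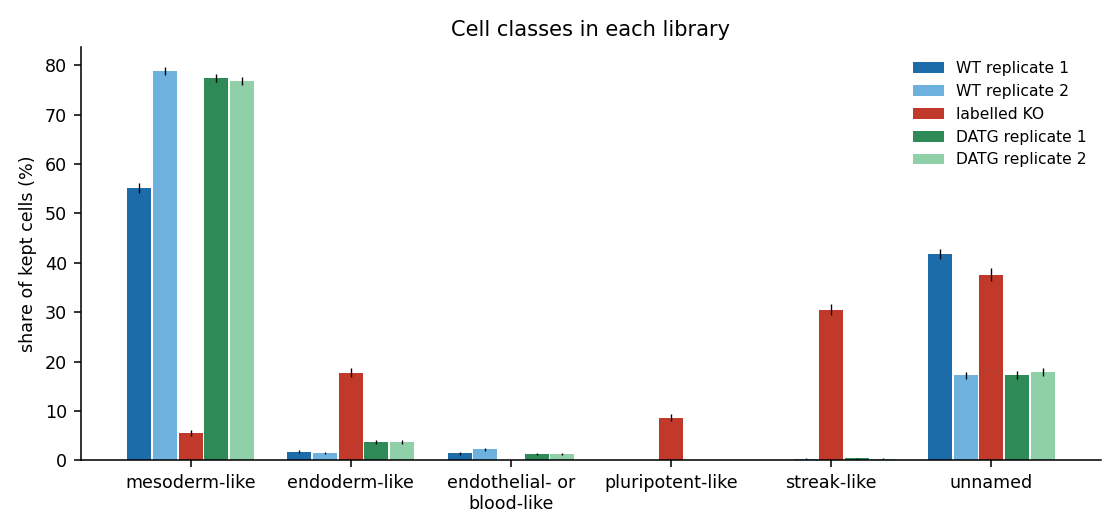
Share of kept cells in each cell class (%, vertical axis) for the 5 libraries (colours); bars start at 0 and the black lines are exact 95% binomial intervals. Mesoderm-like cells fall to 5.50% in the library labelled KO, where streak-like cells reach 30.5%.

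The comparison of DATG with WT asks what differs in gastruloids of the line named for a deleted start codon. LNCPRESS1 counts are too few there to settle its level. The largest differences were losses of single genes. CHCHD2, which encodes a mitochondrial intermembrane-space protein (ENSG00000106153; chromosome 7, 56101569 to 56106576), fell from 142 ± 20.8 CPM in WT to 0.139 ± 0.0228 in DATG (mean ± SD, n = 2 each). Its log2 fold change was −9.99 (SE 0.21, edgeR adjusted p = 0.00170). H19, the imprinted noncoding RNA next to IGF2 (ENSG00000130600; chromosome 11, 1995176 to 2001470), fell from 102 ± 30.7 to 0.359 ± 0.0391 CPM (log2 −8.15, SE 0.30, edgeR adjusted p = 0.00949). PCAT7, a noncoding RNA, fell by 1.29 on the log2 scale (SE 0.09, edgeR adjusted p = 0.0363). NRCAM, a neuronal adhesion molecule, rose by 1.48 (SE 0.10, edgeR adjusted p = 0.0363) and SLCO2A1, a prostaglandin transporter, by 1.17 (SE 0.08, edgeR adjusted p = 0.0362). The neuropeptide gene GAL rose by 1.22 (SE 0.09, edgeR adjusted p = 0.0397) and TTN, the giant muscle protein titin, by 1.08 (SE 0.08, edgeR adjusted p = 0.0405). For each of these 7 genes both DATG libraries lay on the same side of both WT libraries, which the rule for named genes required.

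In all, 22 of 29250 genes passed in DATG against WT by edgeR, 10 higher and 12 lower, and 3559 had an unadjusted p under 0.05. The others include POTEF (log2 −8.11), POTEI (−5.05), CEBPZOS (−3.10), FHL2 (−1.47) and LINC00664 (−2.73), and 4 zinc finger genes, ZNF454 (−3.13), ZNF880 (−2.86), ZNF528 (−2.18) and ZNF562 (−1.31). POTEF and POTEI belong to a family of near-identical copies, so their counts are uncertain. STC2 (2.87), GDF3 (2.39) and CCDC141 (1.61) were higher; these 12 genes were outside the rule for named genes and chosen after their values were seen. The count rests on the spread between the WT libraries. It was 10982 without WT replicate 1, 14516 without WT replicate 2, 171 without DATG replicate 1 and 170 without DATG replicate 2. DESeq2 called 744 and limma-voom 25, while edgeR called 5 with equal weight per cell and 11 with cells thinned, and glmTreat 11.

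**Figure D3:**
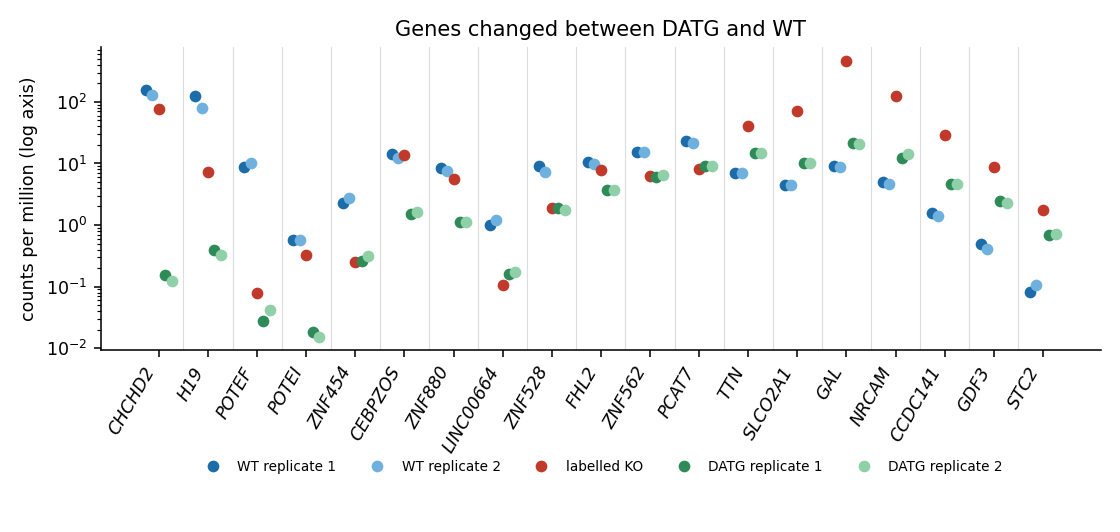
CPM (log axis) of genes that differ between DATG and WT, ordered by log2 fold change; each point is 1 library (colours). CHCHD2 stands at 157 and 128 in WT and 0.156 and 0.123 in DATG, with the library labelled KO at 76.9.

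Of the 32 gene lists, 7 passed in DATG against WT, 4 higher and 3 lower as a set, and 0 did with an estimated correlation (1 at an unadjusted p under 0.05, and 0 by fry). Proliferation genes were higher as a set (camera adjusted p = 3.60e-11, adjusted p = 0.647 with an estimated correlation), though none of the 25 passed alone. Adjusted over the list alone 5 rose, among them AURKA (log2 0.37, SE 0.08) and CCNA2 (0.61, SE 0.13). The definitive endoderm list was higher (camera adjusted p = 0.00249, adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone 4 of its 10 members rose, including the endoderm regulators PRDM1 (1.39, SE 0.17) and FOXA2 (0.96, SE 0.15), and HHEX fell (−1.23, SE 0.18). The pluripotent epiblast list was higher (camera adjusted p = 0.0139, adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone 4 of its 12 members rose, among them ZFP42 (0.56, SE 0.09) and VRTN (0.82, SE 0.14), and SFRP2 fell (−0.55, SE 0.09). FGF and ERK targets were higher (camera adjusted p = 0.0386, adjusted p = 0.759 with an estimated correlation), with 2 of 12 up adjusted over the list alone, ETV4 (0.64, SE 0.10) and SPRY1 (0.82, SE 0.18).

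The endothelial and blood list was lower in DATG (camera adjusted p = 1.28e-04, adjusted p = 0.647 with an estimated correlation). Adjusted over the list alone 4 of 12 fell, among them the vascular regulators ERG (−0.75, SE 0.11), ETV2 (−0.42, SE 0.09) and LMO2 (−0.71, SE 0.16). The 37 HOX cluster genes, which pattern the body axis, were lower as a set (camera adjusted p = 4.08e-04, adjusted p = 0.775 with an estimated correlation), yet none passed over all genes or adjusted over the list alone. The HOX median was −0.30. Imprinted genes were lower (camera adjusted p = 9.65e-05, adjusted p = 0.647 with an estimated correlation); H19 passed over all genes and 4 of 17 fell adjusted over the list alone, including MEST (−0.39, SE 0.09) and NNAT (−0.44, SE 0.08). The count of lists was 16 without WT replicate 1, 11 without DATG replicate 1 and 12 without DATG replicate 2. Of 17 alternatives the call and direction were kept in 7 for the FGF and ERK list, 14 for the pluripotent and for the endothelial list, 15 for the HOX list and 16 for the other 3. The set direction turned to lower for the FGF and ERK list without WT replicate 1 (median 0.05, camera adjusted p = 0.959). It turned to higher for the HOX list without WT replicate 2 (median 0.01, camera adjusted p = 0.742). The other 25 lists had camera adjusted p from 0.0507 to 0.902. The neural, neural crest and cardiac lists had a lower set direction with a mean above 0 (0.32, 0.07 and 0.02). The germ cell, glycolysis and transition lists had a higher one with a median below 0 (−0.05, −0.0048 and −0.05).

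Among cell classes, endoderm-like cells took a larger share in DATG than in WT (log2 ratio 1.23, SE 0.15, edgeR adjusted p = 0.0239 over 6 classes), higher in both DATG libraries than in both WT libraries. The call was kept in 5 of 11 alternatives. It was lost without DATG replicate 1, without DATG replicate 2, with library-centred components and with TMM factors. It was also lost with the replicate number as a block and without the cells high in short-arm UMIs described next. In the last case the log2 ratio was 1.81 (edgeR adjusted p = 0.0521), and a rise of the ratio follows from the removal of cells that are almost all outside this class. Mesoderm-like shares did not differ by more than the WT spread (0.20, SE 0.23, edgeR adjusted p = 0.539), nor did endothelial- or blood-like shares (−0.53, SE 0.31, edgeR adjusted p = 0.370). Within the mesoderm-like class, cluster 4, led by VIPR2, TSLP, ACTC1 and POSTN, held 21.9% and 22.0% of the DATG cells, 4.80% and 3.78% of the WT cells and 1.24% of those labelled KO. Cluster 0 held 22.8% and 39.4% of the mesoderm-like WT cells. The endoderm markers that name the class are among the genes compared, so its share and their levels are 1 observation.

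Genes of the short arm of chromosome 12 were higher as a block in both DATG libraries. Over 135 arm genes with a mean of at least 10 CPM the median log2 fold change of DATG over WT was 0.45 (quartiles 0.34 and 0.54), against 0.02 over 404 genes of the rest of the chromosome. The arm median was −0.06 in the library labelled KO over WT and 0.03 between the WT libraries. Per cell, the share of UMIs on the arm had a second peak in DATG. Cells above 1.9% made up 34.5% and 35.1% of the DATG libraries, 0.806% of WT replicate 2 and 3.15% of the library labelled KO, and 199 of 10476 cells in WT replicate 1. In DATG, 39.2% and 40.1% of mesoderm-like cells lay above it, but 1.61% and 0.756% of endoderm-like cells. The high cells expressed arm genes 1.81-fold and 1.83-fold higher than the other DATG cells, a difference that their selection brings. They held less NRCAM (2.15 and 1.81 CPM against 18.0 and 21.2) and SLCO2A1 (1.89 and 1.16 against 14.5 and 15.1). They held more GAL (38.1 and 34.9 against 11.9 and 11.4) and more GDF3, which lies on the arm (5.66 and 5.14 against 0.526 and 0.478). CHCHD2 and H19 were low in both kinds of DATG cells.

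Without the high cells, 132 genes differed between DATG and WT by edgeR (82 higher, 50 lower), 18 of them among the 22, and 13 lists passed, 6 of them among the 7. GAL no longer passed (log2 0.36; edgeR adjusted p = 0.212), and the endothelial and blood list did not (camera adjusted p = 0.158). CHCHD2 (−9.76), H19 (−8.40), NRCAM (2.04), SLCO2A1 (1.72) and TTN (1.34) did pass. PRDM1 (1.99; edgeR adjusted p = 0.0289), FOXA2 (1.57; edgeR adjusted p = 0.0353) and ETV4 (0.95; edgeR adjusted p = 0.0477) passed over all genes there. The removed cells hold few endoderm-like cells and little NRCAM or SLCO2A1, so rises of these genes and of endoderm genes follow from the removal. The vascular and proliferation changes shrank in this setting. ETV2 went from −0.42 to −0.06, LMO2 from −0.71 to −0.23, AURKA from 0.37 to 0.12, CCNA2 from 0.61 to 0.28 and the proliferation median from 0.31 to 0.17. Over all alternatives, the adjusted p reached 0.354 for TTN, 0.212 for GAL, 0.177 for SLCO2A1 and for PCAT7, 0.166 for NRCAM, 0.0307 for H19 and 0.0157 for CHCHD2. Of 19 alternatives the call was kept in 12 for TTN, 13 for SLCO2A1, 14 for GAL, 15 for NRCAM, 16 for PCAT7 and all for CHCHD2 and H19. This setting was chosen after the data were seen.

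**Figure D4:**
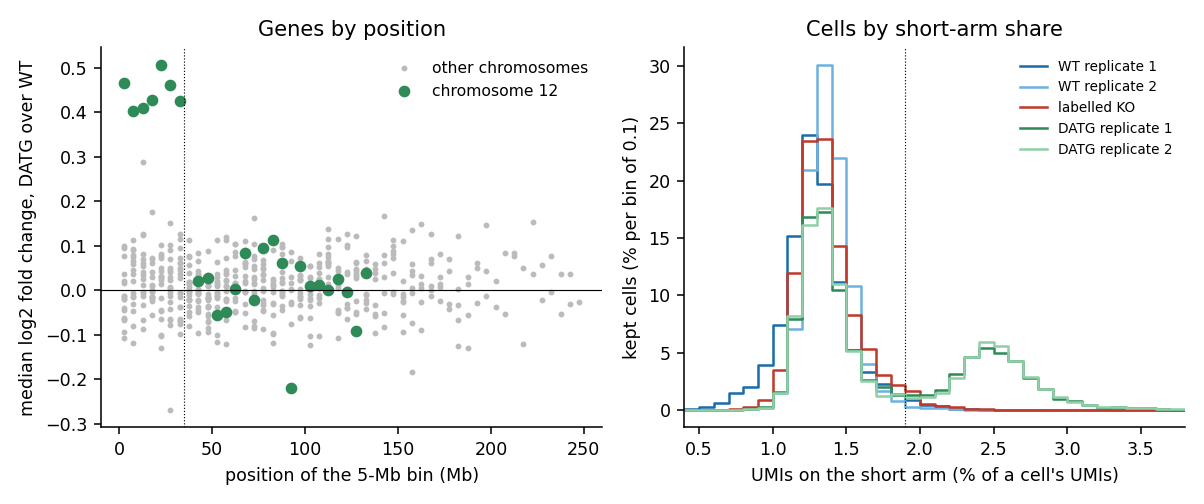
Left, the median log2 fold change of DATG over WT for genes in 5-Mb bins with at least 5 genes along each chromosome (position in Mb), with chromosome 12 in green and a dotted line at the end of its short arm; right, kept cells (% per bin) by the share of their UMIs on that arm, a line per library. The 7 short-arm bins lie between 0.40 and 0.51, above the other bins of at least 5 genes (highest 0.29), and only the DATG lines show a second peak, above 1.9%.

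The comparison of the library labelled KO with WT was meant to ask what loss of lncPRESS1 changes, but the LNCPRESS1 level does not show a loss. All genes of the pluripotent and primitive streak lists were higher in this library. TBXT, the brachyury gene of the primitive streak, rose by 10.24 on the log2 scale (SE 0.20), to 28.1 CPM from 0.0238 ± 0.00551 in WT (SD, n = 2), with an edgeR adjusted p of 1.97e-04. EOMES, a streak and endoderm regulator, rose by 8.65 (SE 0.33, edgeR adjusted p = 2.46e-04) and MIXL1, a mesendoderm factor, by 6.08 (SE 0.18, edgeR adjusted p = 1.97e-04). POU5F1, the core pluripotency factor, rose by 3.83 (SE 0.11), from 16.5 ± 1.14 CPM (SD, n = 2) to 235 CPM (edgeR adjusted p = 1.97e-04). IGFBP3, a secreted growth-factor binding protein, fell by 5.65 (SE 0.23, edgeR adjusted p = 2.65e-04), and POSTN, a matrix protein of mesenchyme, by 5.88 (SE 0.42, edgeR adjusted p = 9.62e-04).

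By edgeR 11284 genes passed, 5648 higher and 5636 lower in the library labelled KO than in WT, and 6769 of them moved more than 2-fold. The count was 19563 without WT replicate 1 and 19871 without WT replicate 2. Other genes with large increases were LINC00458 (log2 8.40), LINC00698 (7.47), MIR302CHG, host of a pluripotency microRNA cluster (6.44, SE 0.96), MESP1, a factor of nascent mesoderm (6.39), NTN1 (5.78) and NTS (5.76). Large decreases included SLN (−8.08, SE 1.34), MGP (−6.94, SE 1.38), AKR1B15 (−6.79), DNM3OS (−5.82), ALOX15 (−5.35) and CLEC1B (−5.21). MIR302CHG, SLN, MGP and CLEC1B also differed widely between the WT libraries, SLN at 376 and 75.5 CPM and MIR302CHG at 4.90 and 0.836. Over the alternatives MIR302CHG ran from 5.63 to 8.19, SLN from −8.82 to −6.50, MGP from −7.68 to −5.37 and CLEC1B from −5.88 to −3.94. The call of MGP was kept in 16 of 17.

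Of the lists 19 passed by camera against WT, and 0 did with an estimated correlation (5 at an unadjusted p under 0.05, and 22 by fry). All 12 pluripotent epiblast genes rose (camera adjusted p = 6.84e-16, adjusted p = 0.196 with an estimated correlation), among them ESRG (log2 8.29) and L1TD1 (4.81). All 10 primitive streak genes rose (camera adjusted p = 1.38e-13, adjusted p = 0.196 with an estimated correlation), with a median of 6.18. In the caudal neuromesodermal list 7 of 8 rose (camera adjusted p = 5.38e-07, adjusted p = 0.223 with an estimated correlation), among them FGF17 (5.86) and WNT3A (4.07). In the presomitic list 8 of 9 rose (camera adjusted p = 4.17e-06, adjusted p = 0.196 with an estimated correlation), such as DLL3 (3.86) and TBX6 (3.65), while RSPO3 fell (−2.31). In the neural list 7 of 8 rose (camera adjusted p = 4.59e-04, adjusted p = 0.294 with an estimated correlation); HES5, at 0.279 CPM in the library labelled KO, was 4.23 higher. Of the endoderm list 6 of 10 rose and 1 fell (camera adjusted p = 2.50e-04, adjusted p = 0.196 with an estimated correlation), with CER1 (4.81), PRDM1 (5.49) and FOXA2 (3.04) up. In the amnion list 4 of 9 rose (camera adjusted p = 0.00992, adjusted p = 0.378 with an estimated correlation), including TFAP2A (3.31). The amnion call was kept in 12 of 16 alternatives, with a median from 0.78 to 1.96. In the germ cell list 4 of 6 rose (camera adjusted p = 0.00625, adjusted p = 0.223 with an estimated correlation), including TFAP2C (2.58). Of the cardiac and lateral plate list 7 of 12 fell and 2 rose (camera adjusted p = 0.00920, adjusted p = 0.223 with an estimated correlation), with HAND2 (−2.55) and TBX20 (−1.63) down. Of the endothelial and blood list 7 of 12 fell and none rose (camera adjusted p = 2.78e-04, adjusted p = 0.196 with an estimated correlation), such as ERG (−4.34) and ETV2 (−3.01). Adjusted over the list alone these counts were the same except in the neural list (7 up, 1 down) and the amnion list (5 up, 1 down).

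**Figure D5:**
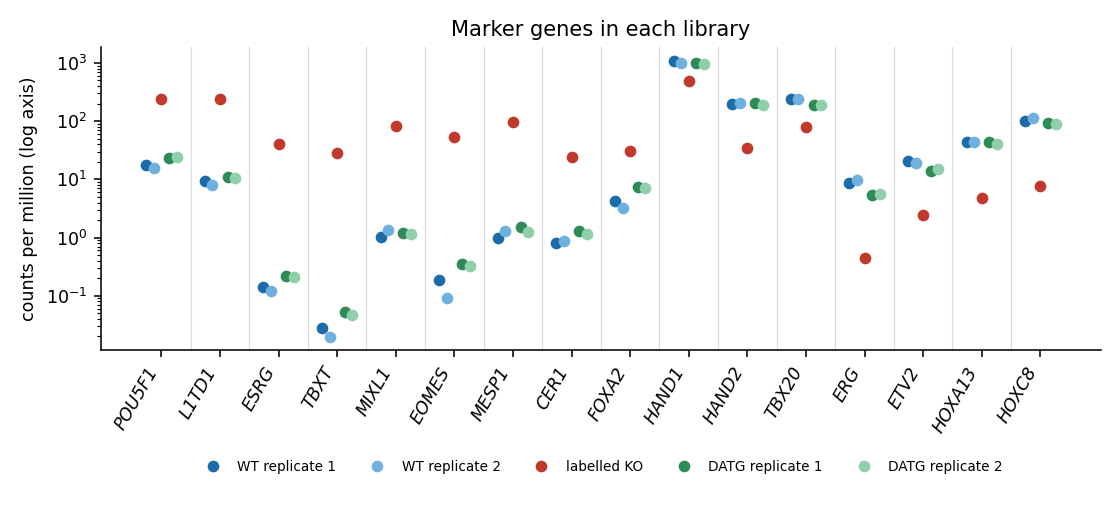
CPM (log axis) of marker genes of pluripotent, streak, endoderm, cardiac, vascular and axial identity; each point is 1 library (colours). In the library labelled KO POU5F1 stands at 235 against 17.3 and 15.7 in WT, and HAND2 at 34.1 against 194 and 206.

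Signalling lists moved in the same library. Of the Wnt targets 12 of 14 rose and 1 fell (camera adjusted p = 3.48e-08, adjusted p = 0.196 with an estimated correlation), including SP5 (log2 4.13), SP8 (3.59) and NOTUM (2.92). Of the Nodal and Activin genes 7 of 10 rose and 1 fell (camera adjusted p = 3.50e-05, adjusted p = 0.196 with an estimated correlation), among them FGF8 (7.22) and GDF3 (4.29). Of the FGF and ERK targets 8 of 12 rose (camera adjusted p = 5.48e-06, adjusted p = 0.196 with an estimated correlation), such as ETV4 (4.08). Of the Notch genes 8 of 12 rose (camera adjusted p = 5.38e-04, adjusted p = 0.196 with an estimated correlation), such as DLL1 (2.06) and NRARP (1.84); adjusted over the list alone 8 rose and 2 fell. Of the proliferation genes 24 of 25 rose (25 adjusted over the list alone; camera adjusted p = 4.94e-10, adjusted p = 0.223 with an estimated correlation), AURKA by 1.06. Of the HOX genes 22 of 37 fell and 3 rose (23 and 3 adjusted over the list alone; camera adjusted p = 3.48e-08, adjusted p = 0.445 with an estimated correlation), HOXC8 by −3.76 and HOXA13 by −3.20. Of the extracellular matrix genes 14 of 18 fell and 3 rose (camera adjusted p = 3.07e-06, adjusted p = 0.196 with an estimated correlation), COL3A1 by −3.44 and FBN1 by −2.58. Ribosomal protein genes were lower as a set (15 of 79 down, 1 up; camera adjusted p = 1.31e-04, adjusted p = 0.687 with an estimated correlation). Nuclear genes of oxidative phosphorylation were also lower (10 of 83 down, 1 up; camera adjusted p = 0.0109, adjusted p = 0.838 with an estimated correlation), NDUFB5 by −0.80; adjusted over the list alone no member of either list passed. The oxidative phosphorylation call was kept in 13 of 16 alternatives, with a median from −0.71 to −0.05.

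The remaining 13 lists did not pass in this comparison (camera adjusted p from 0.0911 to 0.945). Their members that rose and fell were 4 and 2 of 8 for somite, 4 and 2 of 8 for neural crest and 1 and 2 of 6 for notochord. They were 4 and 3 of 11 for BMP targets, 4 and 4 of 11 for retinoic acid, 8 and 5 of 20 for p53 targets and 8 and 5 of 22 for glycolysis. For hypoxia they were 4 and 9 of 16, for dissociation stress 4 and 3 of 16 and for the integrated stress response 3 and 5 of 15. For the epithelial to mesenchymal transition they were 5 and 5 of 11, for imprinted genes 4 and 7 of 17 and for mitochondrially encoded genes 4 and 0 of 13. The notochord list had a lower set direction with a median of 0.20, dissociation stress a lower one with a median of 0.17, and the stress response a lower one with a mean of 0.02.

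The shares of 5 named classes differed from WT in the library labelled KO. Streak-like cells were higher (log2 ratio 7.42, SE 1.67, edgeR adjusted p = 0.0262), as were endoderm-like cells (3.49, SE 0.18, edgeR adjusted p = 0.00141). The endoderm-like ratio ran down to 1.83 over the alternatives (edgeR adjusted p up to 0.0642) and kept its call in 7 of 10. Mesoderm-like cells were lower (−3.60, SE 0.35, edgeR adjusted p = 0.00307), but by less at resolution 1.2 (−1.07, edgeR adjusted p = 0.0450) and with library-centred components (−1.002, edgeR adjusted p = 0.0645). Over the alternatives the call was kept in 6 of 10 for mesoderm-like cells (edgeR adjusted p up to 0.0922) and in 8 of 10 for streak-like cells (up to 0.0574). Pluripotent-like cells, of which WT had none, were at least 271-fold higher (edgeR adjusted p = 0.00141), with WT replicates at the limit of 3 cells per library. Endothelial- or blood-like cells, listed at 0 here, were at least 27.1-fold lower than in either WT library at the same limit (edgeR adjusted p = 0.00299). Of these classes 3 passed without DATG replicate 1 and 3 without DATG replicate 2. The low-gene barcodes and 21.7% of barcodes above 20% mitochondrial UMIs moved with these shares in the same single library.

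The direct comparison of the library labelled KO with DATG asks whether the edited lines differ. With 1 library labelled KO, only a difference between libraries can be shown. TBXT was higher by 9.13 on the log2 scale (SE 0.18, edgeR adjusted p = 2.42e-04), EOMES by 7.28 (SE 0.30, edgeR adjusted p = 3.36e-04) and L1TD1 by 4.52 (SE 0.12, edgeR adjusted p = 2.42e-04) than in both DATG libraries. CHCHD2, near 0 in DATG, was higher by 9.10 (SE 0.21, edgeR adjusted p = 2.42e-04). POSTN (−5.90), IGFBP3 (−5.32) and TSLP (−4.99) were lower. In all 9459 genes passed by edgeR, 4808 higher and 4651 lower. The count was 19770 without WT replicate 1, 19801 without WT replicate 2, 6150 without DATG replicate 1 and 6252 without DATG replicate 2.

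Of the lists, 20 passed in this comparison, 14 higher and 6 lower. With an estimated correlation 0 passed (lowest camera adjusted p = 0.213, 7 at an unadjusted p under 0.05, and 19 by fry). They were the 19 of the comparison with WT and the mitochondrially encoded genes, of which 4 of 13 rose (5 adjusted over the list alone; camera adjusted p = 0.0313, adjusted p = 0.264 with an estimated correlation). The mitochondrial call was kept in 13 of 16 alternatives, with a median from 0.23 to 0.89. All 12 pluripotent epiblast genes and all 10 streak genes rose, and 8 of 12 cardiac genes and 18 of 37 HOX genes fell. NDUFA9, on the chromosome 12 arm that was high in DATG, was among the 7 of 83 oxidative phosphorylation genes that fell (−0.67, SE 0.13). The call of NDUFA9 was kept in 13 of 17 alternatives, with values from −0.77 to −0.14. The call of the oxidative phosphorylation list was kept in 12 of 16, with a median from −0.54 to −0.05. The same 5 classes differed in share: streak-like (log2 ratio 6.53, SE 1.61, edgeR adjusted p = 0.0329), endoderm-like (2.26, SE 0.17) and mesoderm-like (−3.81, SE 0.35), the last 2 with an edgeR adjusted p of 0.00271. The endoderm-like ratio ran down to 0.88 over the alternatives (edgeR adjusted p up to 0.275) and kept its call in 6 of 10. The mesoderm-like ratio was −1.28 at resolution 1.2 and −1.21 with library-centred components. Its call was kept in 7 of 10 and lost without DATG replicate 1, without DATG replicate 2 and with the replicate number as a block (edgeR adjusted p up to 0.117). The streak-like call was kept in 8 of 10 (up to 0.0853). Without DATG replicate 1 or DATG replicate 2, 3 of the 5 passed.

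Comparing cells of 1 class reduces the effect of the mix of classes, but the clusters within a class still differ between groups. In mesoderm-like cells CHCHD2 (log2 −9.98) and H19 (−8.09) were lower in DATG than in WT, GAL (1.33) and the potassium channel gene KCNH1 (1.25) were higher, and 41 genes passed by edgeR (23 higher, 18 lower). This count was 10546 and 12859 without WT replicate 1 and 2, and 145 and 140 without DATG replicate 1 and 2. The 323 mesoderm-like cells labelled KO differed from WT in 297 genes by edgeR (169 higher, 128 lower), with the endocytic receptor gene LRP2 (2.47) up and POSTN (−3.28) and RAMP1 (−3.17) down. Cluster 1 held 5.88% of these cells against 25.4% and 16.1% in WT, and cluster 3 held 23.2% against 7.60% and 14.96%. At resolution 1.2, where 1839 cells labelled KO bore this class name, 4886 genes passed. The count was 6380 and 9217 without WT replicate 1 and 2, and 1400 and 1375 without DATG replicate 1 and 2. Against DATG they differed in 168 genes (92 higher, 76 lower; 6635 and 6411 without WT replicate 1 and 2, 791 and 762 without DATG replicate 1 and 2), and in 3971 at resolution 1.2. Only 7 of those 168 passed without the cells high in short-arm UMIs, which were left out of every library. CHCHD2 was higher by 9.15 and the Wnt antagonist SFRP1 by 2.56.

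In endoderm-like cells CHCHD2 (log2 −10.65), BEX5 (−2.38) and PURPL (−2.38) were lower in DATG, and 12 genes passed by edgeR (2 higher, 10 lower). This count was 2649 and 3732 without WT replicate 1 and 2, and 29 and 37 without DATG replicate 1 and 2. The endoderm-like cells labelled KO differed from WT in 2014 genes by edgeR (1130 higher, 884 lower), with LHX1 (6.45) and LINC00458 (7.82) up and IGFBP3 (−5.81) and GNRH2 (−6.63) down. Here cluster 16 (FGF13, PRDM1) held 354 of the 1043 cells labelled KO and 22 and 12 WT cells. The count was 7462 and 8676 without WT replicate 1 and 2. Against DATG they differed in 1716 genes (1104 higher, 612 lower; 8887 and 8704 without WT replicate 1 and 2, 902 without DATG replicate 1), NTN1 by 5.89 and MTTP by −5.28. In endothelial- or blood-like cells, which the library labelled KO lacked, 18 genes differed between DATG and WT by edgeR (5 higher, 13 lower). CHCHD2 (−9.17) and CCN2 (−2.23) were lower there. H19 was at 88.4 and 58.3 CPM in WT and had no UMI in DATG replicate 1. This last count was 564 and 986 without WT replicate 1 and 2, and 51 and 92 without DATG replicate 1 and 2.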

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

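The tests chosen after the result was seen are both of added undifferentiated cells, of the single culture, of the class mix for CHCHD2 and H19, of other differences between lines, and both tests of a gain of the chromosome 12 arm. The others were chosen before.

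Some effects differed between cell classes by a direct test. For DATG against WT, 3 of 22424 genes changed differently in endoderm-like and mesoderm-like cells by edgeR (2401 at an unadjusted p under 0.05). BEX5 had a difference of −2.76 on the log2 scale (edgeR adjusted p = 0.0281). Its level in endoderm-like cells was 101 and 136 CPM in WT and 23.8 and 22.0 in DATG, with 5.47 and 5.30 against 6.66 and 7.53 in mesoderm-like cells. S100A6 (−1.64, edgeR adjusted p = 0.0281) and NRG1 (−2.06, edgeR adjusted p = 0.0289) also differed. All 3 had a lower DATG level relative to WT in endoderm-like cells. NRG1 fell there from 13.7 and 14.6 CPM to 7.81 and 10.7, and rose in mesoderm-like cells from 4.11 and 4.37 to 10.9 and 12.2. S100A6 in endoderm-like cells was at 65.6 and 22.0 CPM in WT, a wide spread, and at 7.77 and 6.95 in DATG. For the library labelled KO against WT, 2006 genes changed differently between these classes (5532 at an unadjusted p under 0.05). The clusters within each class differed between these libraries. Of the barcodes in the library labelled KO 54.2% held under 1000 genes, more than in any other library, and they enter only the settings with a looser filter.

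The library labelled KO held pluripotent-like and streak-like cells and few mesoderm-like cells. Damaged barcodes are argued against as the source of the pluripotent-like and streak-like cells. Among the deep cells of the library, with at least 10000 UMIs and at most 10% mitochondrial UMIs, these 2 classes made up 58.6%. That test does not cover the low mesoderm-like share. Undifferentiated cells added to a WT-like culture are argued against as the source of the endoderm-like share, which was at least 8.21% of cells outside the pluripotent-like class in every way of forming classes, against at most 1.77% in WT. For mesoderm-like cells they stay open: these were 6.02% of such cells, but 34.3% at resolution 1.2 and 37.0% with library-centred components, against 55.1% and 78.8% in WT. The higher shares do not make these cells WT-like. At resolution 1.2 they came with clusters of 807 and 713 cells labelled KO, which held 0 and 0 cells of WT replicate 1 and 9 and 31 of WT replicate 2. With centred components 1934 lay in a cluster with 0 WT cells. The pluripotent-like class stood for undifferentiated cells here, although it also held streak genes. What else stays open is whether the edit or the culture is the source, because there is 1 library labelled KO and they cannot be told apart.

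CHCHD2 and H19 were near 0 in both DATG libraries. The mix of classes is argued against: the log2 fold change of either gene nearest to 0 in any class was −8.09. Loss of the surrounding region is argued against by genes within 1 Mb, whose median was −0.11 for 8 neighbours of CHCHD2 and −0.12 for 13 neighbours of H19. A difference between cell lines other than the edit, such as silencing of these loci in the founding cells of the line, may be the source, and it cannot be told apart from the edit because the 2 DATG libraries are not named as separate lines and carry 1 shared designation. An effect of the start codon deletion that the name DATG describes is equally a hypothesis, and it was not tested.

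Genes of the short arm of chromosome 12 were higher in both DATG libraries. A gain in the cells of all classes is argued against by endoderm-like cells, where the arm median was −0.0267, and the class mix by mesoderm-like cells, where it was 0.51. Gain of chromosome 12 or its short arm is a known recurrent change of cultured human pluripotent cells, and a gain in part of the DATG cells, which then became mesoderm-like, is a candidate explanation. The test set for it could not decide it, because a cluster median pools high cells with others. The lowest median of a mesoderm-like cluster exceeded the highest of an endoderm-like or endothelial-like one by only 0.0422. Mesoderm-like clusters ranged from 0.13 in cluster 0, where 5.18% and 4.67% of DATG cells were high, to 0.80 in cluster 4, where 81.7% and 81.9% were. A gain in part of the cells need not reach every mesoderm-like cluster, and RNA does not measure DNA copies.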

How the results depend on the processing

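The settings without high short-arm cells, without short-arm genes and with at least 10000 UMIs were chosen after the data were seen; the others were planned. Unless a cause is named, the cause was not tested. Of the named genes' 1149 alternative values for the library labelled KO against WT, 1143 kept direction and side of the threshold and 6 no longer passed; against DATG 1090 of 1113 kept both and 23 no longer passed. For DATG against WT 425 of 530 did, 25 no longer passed, 75 newly passed and 5 reversed, all of LNCPRESS1. Leaving out a WT library leaves the DATG pair, with its small spread, to set most of the error, so those counts are large by construction.

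For DATG against WT the count of 22 genes became 85 with no count filter, 52 with stricter cells, 5 with equal weight per cell, 11 with cells thinned, 132 without high short-arm cells, 744 by DESeq2 and 11 by glmTreat. It was 18 to 14516 with a library left out. Lists (7) were 13 without high short-arm cells and 7 to 16 with a library left out. By estimated correlation 0 lists passed in each comparison, with 1, 5 and 7 at an unadjusted p under 0.05 (fry 0, 22 and 19) for DATG against WT, the library labelled KO against WT and against DATG. The median of FGF and ERK targets ran from 0.0485 to 0.51 and that of HOX genes from −0.54 to 0.00954 with a library left out, and each list turned its set direction in 1 of these settings. LNCPRESS1 in DATG against WT reversed to −0.15 thinned, −0.00367 with at least 10000 UMIs and −0.32 without high short-arm cells, and ran from −0.12 to 0.27 with a library left out; its counts are too few to give a direction. In the library labelled KO, glmTreat gave 6382 genes against WT and 5195 against DATG, since it asks for a larger change. With a library left out these counts ran from 9072 to 19871 and from 6150 to 19801.

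Class shares of DATG against WT (1 call) had 0 calls by edgeR with library-centred components, without high short-arm cells and with TMM factors, each with 1 class at an unadjusted p under 0.05, and 0 to 4 with a library left out (0 without either DATG library, none at an unadjusted p under 0.05). With centred components the pluripotent-like and streak-like classes held 0 WT and 0 DATG cells, so their log2 ratios were 0 and have no direction. Log2 ratios reversed to 0.0426 for endothelial-like shares without high short-arm cells and to −0.0044 for mesoderm-like shares with TMM factors. With a library left out, the mesoderm-like ratio ran from −0.0313 to 0.48 and the streak-like from −0.0459 to 4.01. For the library labelled KO the counts were 3 against WT and 3 against DATG with at least 500 genes and doublets kept, 3 and 3 with TMM factors, and 3 to 6 and 3 to 6 with a library left out.

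Within mesoderm-like cells resolution 1.2 gave 4886 genes for the library labelled KO against WT and 3971 against DATG; without high short-arm cells the last was 7. With a library left out the mesoderm-like counts ran from 40 to 12859 for DATG against WT, 1375 to 9217 for the library labelled KO against WT and 762 to 6635 against DATG. The endoderm-like counts ran from 9 to 3732, 1648 to 8676 and 902 to 8887 in the same order. Endothelial-like counts were 29 at resolution 1.2 and 51 to 986 with a library left out.

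With the replicate number as a block, DATG against WT gave 946 genes, 12 lists and 0 class shares (none at an unadjusted p under 0.05 by edgeR), and the library labelled KO against DATG 3 class shares. In mesoderm-like cells the block gave 1226, 3051 and 2234 genes for the 3 comparisons, in endoderm-like cells 70 for DATG against WT and in endothelial-like cells 190. The numbers pair nothing that the data show: replicate 1 deviations of WT and DATG correlated at 0.113 across 9842 genes, which are not independent replicates.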

Other observations

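The tests of zinc finger genes and of the DATG cells high in short-arm UMIs were chosen after the result was seen; those of neighbours of LNCPRESS1 and of whole chromosomes were chosen before.

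The DATG cells with over 1.9% of their UMIs on the short arm of chromosome 12 differed from the other DATG cells in class. Mesoderm-like cells made up 88.0% and 87.8% of them in DATG replicates 1 and 2, against 71.7% and 71.0% of the others. Endoderm-like cells made up 0.172% (exact 95% interval 0.0632% to 0.375%) and 0.0806% (0.0166% to 0.235%), against 5.54% and 5.73%. Of cluster 4 in DATG, 81.7% and 81.9% were such cells. They held more of the receptor gene VIPR2 (42.3 and 43.2 CPM against 19.3 and 20.7 in the others) and less SOX17, an endoderm factor (0.358 and 0.245 CPM against 11.05 and 10.86). NANOG, a pluripotency factor on the arm, stood at 0.179 and 0.252 CPM against 0.307 and 0.394.

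Genes changed in DATG were mostly changed the same way in the library labelled KO. Of the 22, 20 were (10 of 10 higher and 10 of 12 lower), where independent lists of these sizes would share 4.24. Both comparisons use the same WT libraries, so the lists are not independent. Over 9842 genes the covariance of the log2 fold changes of both comparisons was 0.103, against at most 0.0140 in 20 simulations with shared WT libraries and no effect. The Pearson correlation was 0.452, against a median of 0.400 and at most 0.423 in the simulations. With no effect simulated, the shared WT libraries fix that correlation by design, so it cannot be set against the observed one. The spread of the simulations was pooled over the groups, and the WT pair varied more than the DATG pair, so they may understate the shared WT noise. How much of the overlap of called genes the shared libraries bring stays open. For 8 of the 22 (6 lower, 2 higher) the library labelled KO did not differ detectably from DATG, among them ZNF454 (0.254 CPM against 0.261 and 0.311) and ZNF528 (1.87 against 1.87 and 1.78).

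Of the 12 genes lower in DATG 4 are zinc finger genes, a family with 467 of the 29250 genes tested, and 3 of the 4 lie on chromosome 19. A one-sided Fisher's exact test gave p = 2.87e-05, but the family was singled out because these genes had been seen, so the value restates the observation and decides nothing. The family as a whole did not move, with a median log2 fold change of −0.01.

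Of the 26 genes within 500 kb of LNCPRESS1, 0 passed by edgeR in DATG against WT, 1 had an unadjusted p under 0.05, and DESeq2 called 0 and limma-voom 0. Only 0.0752% of all genes passed in this comparison, and few small changes are recovered, so a count of 0 was near certain and leaves an effect on neighbours open. In the library labelled KO 17 of the 26 (65.4%) passed against WT and 14 against DATG, where 38.6% and 32.3% of all genes did. The hypothesis that a whole chromosome was gained or lost in DATG was argued against by the chromosome medians, of which the largest in size was 0.0658; that test is too coarse to see the short arm of chromosome 12.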
